A study of Homo sapiens with 2 samples.

How the data were processed

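Gene expression was measured in stable derivatives of C33-A, an established human cervical carcinoma cell line that carries no papillomavirus. One line had been transfected with the full-length cDNA of CA9, which encodes carbonic anhydrase IX, a membrane-bound enzyme that hydrates carbon dioxide and is induced in hypoxic tumours. The other line carried the empty vector. Per the labels' protocols, cells were grown in medium with 10% serum, RNA was taken on day 4 after seeding, and biotinylated cRNA was made from 5 µg of total RNA and hybridised to Affymetrix arrays. There was 1 array per line. The labels do not say whether a line is a single clone or a pool.

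The deposited table gives 1 intensity per probe set and array. The authors' values were made with RMA, per the submitters' processing notes, and no version, background setting or build of the probe definitions is given in the sources used here. RMA ordinarily returns log2 values, and the deposited intensities are on a linear scale, from 6.79 to 17091 on the CA9 array and from 7.19 to 16842 on the vector array, so they were put on log2 without a pseudocount. The linear scale is read from the values; the plan for the comparison had assumed log2 values. The median intensity was 41.8 on the CA9 array and 40.1 on the vector array, so the columns are close in distribution but not identical. In 1425 of 54675 probe sets the values of both arrays were exactly equal.

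Gene names came from a platform annotation table. It lists 42898 of the probe sets, of which 41097 have 1 gene symbol and 1801 have several. Probe sets with several genes were not named, and 11721 probe sets other than controls are not listed there and stay unnamed here. Entrez identifiers of 41043 single-gene probe sets matched the RefSeq gene table of assembly GRCh38.p14, which updated the symbols and gave the order of neighbouring genes. No coordinates are given, since the array values carry no genome build. The table pairs no probe set with CA9, so the level of the transgene was not analysed here and does not check the labels.

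A gene was represented by the single-gene probe set with the highest mean log2 intensity. The floor was the median of all probe sets other than controls over both arrays, an intensity of 40.8, and a gene was measurable if its higher array lay above it. That left 13823 of 19775 genes. The difference is log2 of the CA9 line minus log2 of the vector line, and a gene was called by size, at 2-fold or more. Where the lower array lay at or below the floor, the fold is given against the floor as "at least". With 1 array per line there is no replicate, so no p-value, standard error or test of a difference is given, and every value describes these 2 arrays. The number of arrays limits the precision. As a measure of technical disagreement, deviations of the log2 differences of probe sets above the floor from the mean of their gene were pooled over 6186 genes. This SD between probe sets was 0.31. Probe sets of a gene share the RNA and the array, so they are not replicates. Other probe sets of a gene are described where they lie above the floor, whereas an average over the probe sets of a gene takes in those below it.

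The median difference of each of 29 gene lists, written before the data were examined, was set against 10000 random lists of the same size drawn from the same 20 bins of mean intensity. Of these lists, 1 entered the counts of lists but is not reported here. A list was described as standing apart below the 2.5th or above the 97.5th percentile. The share of random lists with as many called members was added after the data were seen. Among the 29 lists it is given only for the 4 whose count of called members lay above the 97.5th percentile of random lists. The named genes were fixed by rule at the same time: CA9, the 12 called genes with the largest positive and the 12 with the largest negative difference, passing over those whose other probe sets mostly had the opposite sign and using probe sets named _x_at only where a gene had no other, then up to 3 called members of each list, filled up to 2 with the members farthest from 0 where fewer were called. All members of a list beyond the 1st or 99th percentile could be named. The order by difference is not settled for values below the floor. Of these 24 genes, 1 is not reported here. Genes chosen after their values were seen are named as such.

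Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures used matplotlib 3.10.9. The 2-fold rule was tested on simulated differences of 13823 genes, in which 200 genes, 50 per fold, were shifted and noise had the SD between probe sets. It called 14% of genes shifted 1.5-fold, 52% of genes shifted 2-fold, 90% of genes shifted 3-fold and 100% of genes shifted 4-fold, and 0.147% of unshifted genes. The choice of probe set, the floor, a spread that varies with intensity and the spread between cultures or arrays were not simulated. These shares are therefore not error rates of the calls. Of 1000 random lists of 30 genes drawn from the measured differences, 4.5% fell beyond the outer percentiles. Alternatives were the mean over a gene's probe sets, leaving out probe sets named _x_at or _s_at, equal medians, quantile normalization, removal of a loess trend, no floor, a floor at the 75th percentile, both arrays above the floor, thresholds of 1.5-fold and 3-fold, and random lists not matched on intensity. Matching on gene density, removal of a drift with gene density and a scan of gene families were added after the data were seen.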

Results

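The data comprise the array profile of C33-A cells that carry the CA9 cDNA and that of C33-A cells that carry the empty vector, 1 array each. The comparison asks which genes differ in expression between the CA9 line and its vector control. The log2 intensities of 13823 measurable genes had a Pearson correlation of 0.974 across genes, which are not independent replicates, and the differences had a median of -0.03 and an SD of 0.38. The log2 differences of a gene's probe sets had a pooled SD of 0.31 around the mean of the gene. There were no replicates, so a difference between the lines cannot be told from the spread between cultures of one line.

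In the CA9 line 90 genes were at least 2-fold higher and 96 were at least 2-fold lower than in the vector line, together 1.35% of measurable genes. In 60 and 67 of them both arrays lay above the floor. Setting the medians of the arrays equal gave 69 higher and 123 lower genes, so that the share of higher genes among the calls was 35.9% in place of 48.4%. Averaging the probe sets of a gene, dim ones included, gave 44 higher and 48 lower genes. The higher genes named here encode secreted, membrane and structural proteins as well as enzymes, and the lower genes include a receptor, a microRNA host transcript, an enzyme of haem synthesis and a desmosomal protein. Of the 186 called genes, 78 had another probe set above the floor. In 69 of them at least 1 other probe set had the same sign, and in 27 it also passed 2-fold. Of the 96 lower genes 80 lay in gene-poor regions, against 32 of the 90 higher genes, where gene-poor means the 40% of genes with the fewest protein-coding genes within 500 kb.

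ALDH1A1, a retinaldehyde dehydrogenase, was 9.00-fold higher in the CA9 line, at an intensity of 1102 against 122. DKK1, which encodes a secreted inhibitor of WNT signalling, had an intensity of 234 in the CA9 line and 17.1 in the vector line, which lies below the floor, so that it was at least 5.73-fold higher. ANXA1, a calcium-dependent phospholipid-binding protein, was 7.11-fold higher, at 1732 against 244, and the average over its probe sets was 1.77 on the log2 scale. EMP1, an epithelial membrane protein, was 6.89-fold higher, at 2245 against 326, and its 3 other probe sets were all more than 2-fold higher too, 1 with a log2 difference of 2.43 and the others at least 6.31-fold and at least 6.87-fold against the floor. The average of EMP1 with dimmer probe sets was 2.07. MYOT, a protein of the muscle Z-disc, was at least 2.55-fold higher, at 104 against 16.5.

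TFPI2, a Kunitz-type protease inhibitor, was 3.90-fold higher, with a log2 difference of 1.96 and of 1.33 in a second probe set. NEFH, the heavy neurofilament subunit, was 3.60-fold higher, and its second probe set had a log2 difference of 2.07. CHCHD10, a mitochondrial protein, was 3.31-fold higher. GARIN4 was 3.42-fold higher in its brightest probe set, while its other probe sets had log2 differences of 0.18 and -0.32 and the average was 0.54. ADAM2, a sperm surface protein, and the non-coding LINC00857 had intensities of 57.9 and 79.9 in the CA9 line. Both were below the floor in the vector line, and they were at least 1.42-fold and at least 1.96-fold higher.

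Among the lower genes, GPR15, a G protein-coupled receptor, had an intensity of 25.3 in the CA9 line and 706 in the vector line, and was at least 17.3-fold lower. MIR100HG, the host transcript of a microRNA cluster, had 11.9 against 217 and was at least 5.32-fold lower, with an average over its probe sets of -1.91. ANKRD1, an ankyrin-repeat protein, was 10.1-fold lower, at 272 against 2738. CPOX, coproporphyrinogen oxidase of the haem pathway, was 7.26-fold lower, at 358 against 2599. ENC1, a kelch-family protein that binds actin, was 4.93-fold lower, with a second probe set at least 4.31-fold lower against the floor.

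OGFRL1 was 4.15-fold lower, with a second probe set at -1.53 and another at least 2.54-fold lower, and CLDND1 was 3.86-fold lower, with a second probe set at -2.69 and an average of -1.19. DSP, which encodes desmoplakin, a plaque protein of desmosomes, was 3.64-fold lower, at 49.4 against 180.0. The non-coding LINC00052 was 3.82-fold lower. RGS20, a regulator of G protein signalling, was 3.72-fold lower in its listed probe set and had a log2 difference of -0.25 in another and an average of -1.07. EID3 was at least 3.11-fold lower. The cytidine deaminase gene APOBEC3B was at least 2.46-fold lower, and its probe set is of a kind (_s_at) that can also detect related transcripts.

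**Figure D1:**
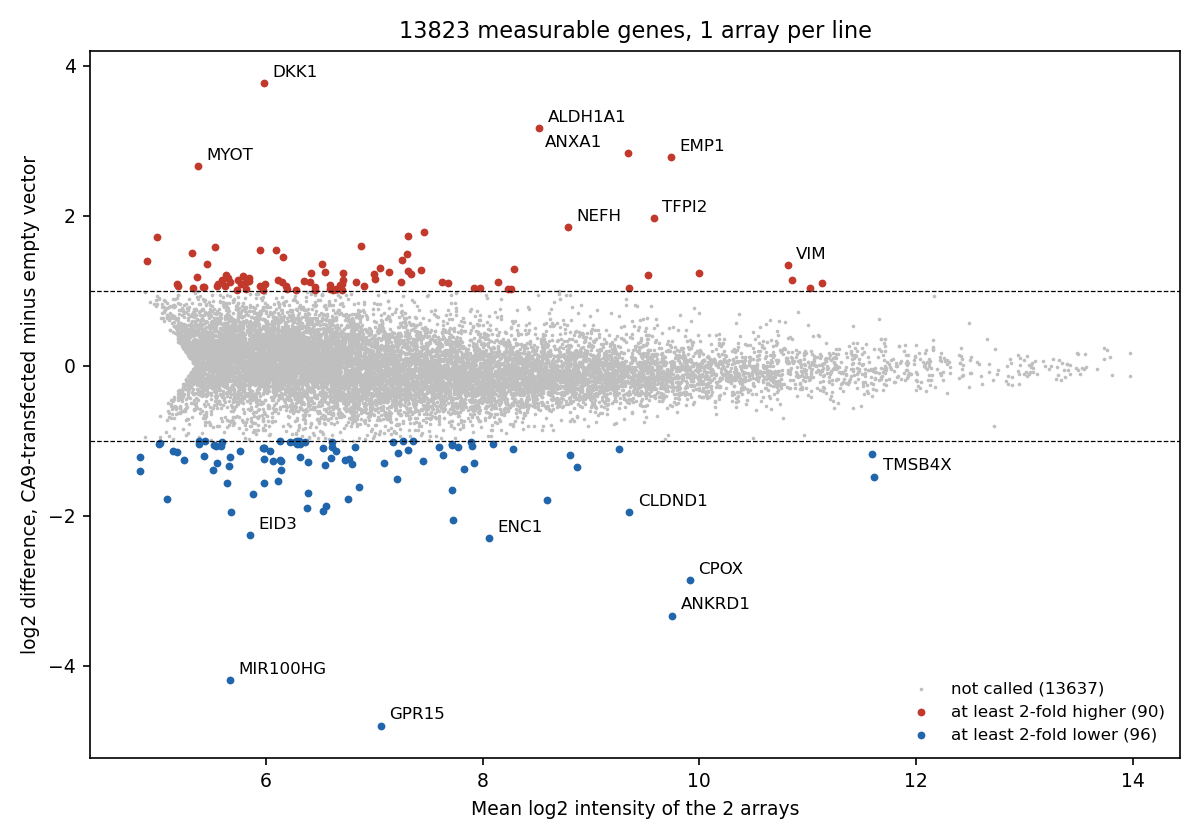
Each point is 1 of 13823 measurable genes, with the mean log2 intensity of the 2 arrays on the horizontal axis and the log2 difference, CA9 line minus vector line, on the vertical axis. Red points mark the 90 genes at least 2-fold higher and blue points the 96 at least 2-fold lower, and dashed lines mark 2-fold.

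**Figure D2:**
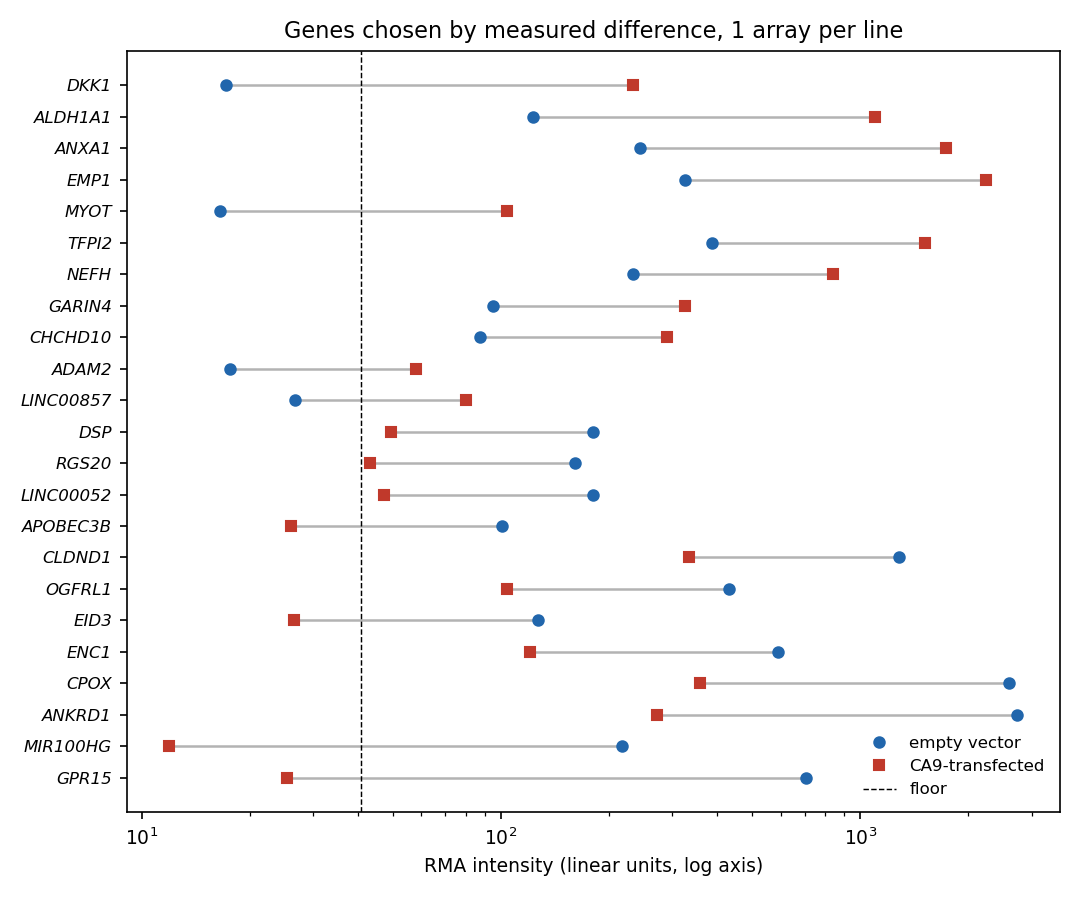
RMA intensity on a log axis of the genes chosen by the size of their measured difference, with circles for the vector line, squares for the CA9 line and a dashed line at the floor of 40.8. DKK1, MYOT, ADAM2 and LINC00857 lay below the floor in the vector line, and GPR15, MIR100HG, EID3 and APOBEC3B lay below it in the CA9 line.

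Genes regulated by hypoxia were lower as a list in the CA9 line. The median log2 difference of the 32 measurable hypoxia and HIF targets was -0.22, below all but 0.58% of random lists, and 11 of the 32 were above 0. The glucose transporter SLC2A3 was the only called member, 2.37-fold higher at 216 against 91.3, with other probe sets at 0.37 and 1.01. Members with negative differences, all short of 2-fold, included the peptide hormone gene ADM at -0.65, the mTORC1 inhibitor DDIT4 at -0.63, the histone demethylase KDM3A at -0.56, MXI1 at -0.49 and the adenylate kinase AK4 at -0.49. The average over its probe sets was 0.87 for SLC2A3. The list's median was -0.12 (percentile 5.06) when the probe sets of a gene were averaged, and -0.16 (percentile 13.7) without probe sets named _x_at or _s_at, where 20 members remained. With the brightest probe set of each gene, 1 of the 29 lists stood apart, and 1.45 would do so among random lists. Averaged probe sets gave 3 such lists, not including this one, and a floor at the 75th percentile gave 5.

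None of the 27 measurable carbonic anhydrases and acid-base transporters was called, and the list's median was 0.14, at percentile 96.0. The largest differences were 0.78 for CA4 and 0.74 for SLC4A2, an anion exchanger, and 17 of the 27 were above 0. Over 9 alternative settings this list's median ran from -0.15 to 0.15 and its percentile from 38.5 to 97.9, and it stood apart in 1. Of 19 glycolysis genes, PKM (pyruvate kinase) was called, 2.04-fold higher at 2962 against 1450, with a second probe set at 0.29. Its average was 0.66, and it was 0.97 with the medians of the arrays set equal, both short of 2-fold. The list's median was -0.03. No member of the 31 oxidative phosphorylation genes was called, and NDUFB3 at -0.45 and NDUFB8 at -0.44 were farthest from 0.

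In the actin cytoskeleton list, TMSB4X, the actin monomer-binding thymosin, was 2.79-fold lower at 1875 against 5233, in a probe set named _s_at. No other of the 41 genes was called, and the list's median was 0.00 (percentile 92.0). Over the alternatives that median ran from -0.06 to 0.08 and its percentile from 65.5 to 99.9, and the list stood apart in 1 of 9. Of 28 integrin and focal adhesion genes TLN1, which encodes talin, was called higher at 1.36, but both of its other probe sets lay below 0, 1 at -0.42 and 1 with the CA9 line below the floor, and the average was 0.24. Of 29 cell-cell junction genes, DSP and the protocadherin gene PCDH9 were called lower, PCDH9 by 3.42-fold in a probe set named _s_at. Without such probe sets PCDH9 had a difference of 0.03, and its average was -0.56. The junction list had a median of -0.05 (percentile 23.9) and the focal adhesion list one of -0.08 (percentile 26.6). Both depended on the setting and each stood apart in 1 of 9 alternatives: the junction median ran from -0.27 (percentile 1.10) to 0.04 (percentile 75.6), and the focal adhesion median from -0.30 (percentile 0.86) to 0.13 (percentile 96.2).

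Of 18 mesenchymal genes, VIM, the intermediate filament vimentin, was 2.53-fold higher at 2867 against 1131, in a probe set named _s_at. THBS1, thrombospondin, was 3.17-fold lower. Its 3 other probe sets were lower too, 1 of them with the CA9 line below the floor. With dimmer probe sets averaged in, both fell short of 2-fold, at 0.78 for VIM and -0.89 for THBS1. The median of this list was 0.15 (percentile 94.6), and 2.91% of random lists had as many called members. In the list of 38 extracellular matrix and protease genes the collagen gene COL4A1 was 2.03-fold lower, with a second probe set at -0.02. It fell short of 2-fold after quantile normalization (-0.96), loess removal (-0.94) and averaging (-0.52), and the list's median was 0.00. None of 30 keratins and epithelial genes was called (median 0.14), and KLF4 and S100A7, below the floor in the vector line, were at least 1.42-fold and at least 1.24-fold higher. Over the alternatives the keratin list's median ran from -0.20 to 0.14 and its percentile from 27.4 to 98.6, the lower end with 5 members left at the higher floor, and it stood apart in 1 of 9.

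Among signalling lists, the 29 WNT pathway genes had a median of 0.16 (percentile 95.4), with DKK1 as the only called member and WNT5B at least 1.61-fold higher and WNT5A at least 1.52-fold lower against the floor. Over the alternatives the WNT median ran from 0.04 to 0.16 and its percentile from 67.4 to 99.3, and it stood apart in 2 of 9. Of 31 TGF-beta and BMP genes the BMP antagonist GREM1 was called higher, at least 1.19-fold against the floor. The list's median was -0.12 (percentile 11.6). Over the alternatives it ran from -0.22 to -0.06 and its percentile from 1.08 to 41.5, and it stood apart in 2 of 9. Of 37 receptor kinases, ligands and feedback genes, the growth factor FGF9 was 3.25-fold lower at 46.4 against 151, with an average of -1.03, and the median was -0.05. None of 21 immediate early genes was called (median -0.08), with JUN at -0.83 and KLF4 at least 1.42-fold higher against the floor. In the 16 NF-kB targets and cytokines, TNFAIP3, an inhibitor of NF-kB signalling, was 2.42-fold lower in a probe set named _s_at. It was short of 2-fold as an average (-0.84), and the list's median was 0.09.

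The proliferation list had 56 measurable genes and a median of -0.08 (percentile 59.1). CCND2, cyclin D2, was called, at least 2.57-fold higher against the floor, with a second probe set at 0.07 and an average of 0.49, and no other member was called. None of the 29 p53 target and cell death genes was called (median -0.15, percentile 9.62), and DAPK1 at -0.79 was farthest from 0. The p53 list's percentile ran from 0.78 to 27.2 over the alternatives, and the list stood apart in 3 of 9. Of 30 genes of the unfolded protein response and amino acid stress none was called (median -0.10), with ATF3 at -0.80. Of 15 heat shock genes none was called (median 0.01), with HSPA13 at -0.93. Of 22 interferon response genes IFIT5 was 2.03-fold lower, with a second probe set at -0.24 and an average of -0.63. The list's median was -0.12 (percentile 4.76). Over the alternatives the interferon median ran from -0.26 to -0.03 and its percentile from 0.80 to 22.4, and it stood apart in 3 of 9.

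The cholesterol and fatty acid list held a called gene in each direction among 26. HMGCS1, an enzyme of the mevalonate pathway, was 2.24-fold lower, with a second probe set at -0.51, and FASN, fatty acid synthase, was 2.06-fold higher, with a second probe set at 0.73. Their averages were -0.84 and 0.88, HMGCS1 was at -0.51 without probe sets named _x_at or _s_at, and FASN was at 0.98 with equal medians. The list's median was -0.13 (percentile 35.3), and 2.21% of random lists had as many called members. Of 28 metallothionein and oxidative stress genes, TXNRD1, thioredoxin reductase, was 2.25-fold lower at 2059 against 4642, but short of 2-fold as an average (-0.60). The list's median was -0.05 (percentile 58.6). Over the alternatives it ran from -0.29 to -0.01 and its percentile from 0.53 to 67.5, and it stood apart in 2 of 9. No ribosomal protein gene of 26 was called (median -0.06).

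The neuronal and neuroendocrine list had 3 called members among 13, and 0.03% of random lists had as many. NEFH and MAP2, a microtubule-associated protein, were higher, MAP2 by 2.36-fold at 1573 against 666 with a second probe set at 0.99, and the adhesion molecule NRCAM was at least 1.90-fold lower against the floor, with an average of -0.72. The median was 0.20, at percentile 97.4. It was 0.03 (percentile 70.8) with averaged probe sets and -0.02 (percentile 24.9) with no floor, and 0.56, above all random lists, with the floor at the 75th percentile, where 7 genes remained. It stood apart in 5 of 9 alternatives. Of 16 stem and germ-cell genes, ALDH1A1 was higher and its relative ALDH1A3 was 2.39-fold lower, at 45.3 against 108, with an average of -0.58. That median was 0.04 (percentile 73.0), and 1.64% of random lists had as many called members.

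Markers of other cell types gave no called gene. The 11 measurable blood cell markers had a median of 0.21 (percentile 83.7), with PTPRC at least 1.42-fold lower and CD14 at least 1.40-fold higher against the floor. The list stood apart in 1 of 9 alternatives, and 1 member was left with the floor at the 75th percentile. The 10 fibroblast and endothelial markers had a median of 0.12 (percentile 75.5), with THY1 at 0.55 and PECAM1 at 0.39. The 13 markers of kidney, liver and breast lines had a median of 0.15 (percentile 64.2), with WT1 at 0.61.

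**Figure D3:**
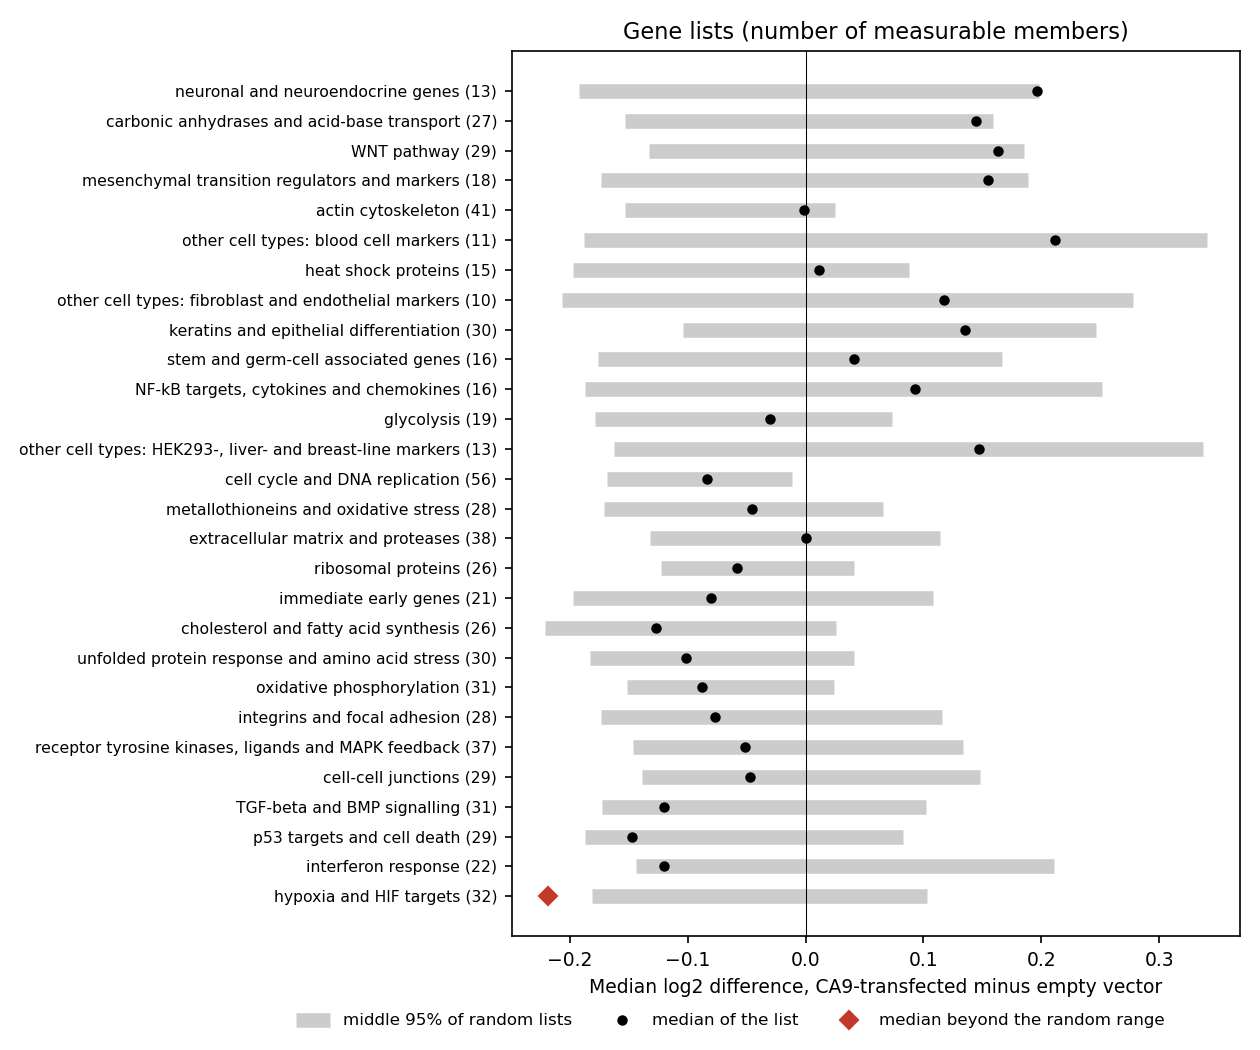
Median log2 difference, CA9 line minus vector line, of each gene list reported here, with the number of measurable members in brackets. Grey bars span the middle 95% of 10000 random lists matched on intensity, and the hypoxia and HIF target list, drawn as a diamond at -0.22, lies outside its bar.

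Control probe sets described the RNA and the hybridisation of each array. The 3' minus 5' log2 signal of the ACTB control was 0.67 on the CA9 array and 0.73 on the vector array, and that of GAPDH was 0.06 and 0.04. The bacterial spike-ins for hybridisation were higher on the CA9 array, with a median log2 difference of 0.41 and 17 of 18 probe sets above 0, and the poly-A spike-ins had a median of -0.20, with 3 of 24 above 0. All 3 probe sets for 18S ribosomal RNA were lower on the CA9 array, by log2 differences from -2.15 to -0.92. For 28S ribosomal RNA the intensities were 98.9 against 667 at the 5' end, 897 against 1701 in the middle and 97.8 against 80.1 at the 3' end.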

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

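The test of RNA degradation, and the division of genes by gene density, were chosen after the values were seen. Among probe sets left out of the comparison because they carry no gene name here, 26 above the floor were at least 2-fold higher and 26 at least 2-fold lower in the CA9 line. The hybridisation spike-ins, which no comparison used, were higher on the CA9 array than on the vector array by a median of 0.41 on the log2 scale.

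Of the 186 genes at least 2-fold apart, 78 had another probe set above the floor, and the next-brightest lay on the same side of 0 in 83.3% (Wilson 95% interval 73.5 to 90.0%), against 62.1% of genes that were not called. Noise alone was taken to give at most 60%, a bound that the genes not called already passed. The interval includes the 80% that was to exclude noise, and it treats genes of the same arrays as independent, which they need not be. Of the called genes, 108 had no second probe set. Probe sets of a gene also share the RNA and the array, so how many calls are noise stays open. Gain or loss of segments long enough to shift the median of 41 neighbouring genes is argued against as the main source. Such windows, beyond all 1000 shuffles of gene order, held 2.69% of called genes in their direction and 0.724% of measurable genes. A segment cause stays open for the 5 lower genes among the 56 from ARRDC3-AS1 to PRDM6. The other segment, 44 genes from S1PR4 to TICAM1, was higher by a median of 0.33 after the trend with intensity was removed, and held 0 called genes. The drift with gene density described below was not removed from the windows, so it stays open as a source of both segments. Windows of this length do not register a change that covers only a few neighbouring genes. Shorter segments therefore stay open, and called genes that lie next to one another need not be independent. Different RNA degradation stays open, since ACTB and GAPDH alone cannot speak for the called genes. Their 3' minus 5' log2 signal differed between the arrays by at most 0.069. That of 18S ribosomal RNA differed by 0.77 and that of 28S by 3.04. On the vector array, however, 28S was brighter at its 5' end than at its 3' end (667 against 80.1), so the ribosomal values do not settle it. An effect of CA9 cannot be separated from other differences between 2 lines that were selected once each.

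Genes lower in the CA9 line lay mostly in gene-poor regions: 80 of 96, or 83.3%, were in the 40% of genes with the fewest protein-coding genes within 500 kb, against 32 of 90 higher genes. Across all genes the median difference, after the trend with intensity was removed, ran from -0.08 in the gene-poorest of 5 equal groups to 0.10 in the densest. The intensity of such genes is argued against, since 39.9% of random genes matched on intensity lay there and the highest of 1000 draws was 57.3%. After the drift with gene density was subtracted, 73.7% of 76 lower genes still lay there, against 48.8% of 84 higher genes. The interval for the lower genes, 62.8 to 82.3%, also treats genes as independent. The SD of the differences was wider in the gene-poorest group than in the densest (0.427 against 0.333). These values leave open how much of the pattern the drift and the spread account for. Base composition, which follows gene density, may underlie the drift as a labelling or hybridisation effect, but no probe or transcript sequences were used here, and an effect of CA9 stays open, untested.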

How the results depend on the processing

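The alternatives on gene density were chosen after the data were seen. Counts moved by over 1.5 times under these settings: averaging the probe sets of a gene gave 44 higher and 48 lower genes, of which 39 and 47 were among the original 90 and 96; the floor at the 75th percentile gave 56 higher genes; a 1.5-fold threshold gave 731 and 655, and a 3-fold threshold 11 and 19. Under the other settings the counts stayed within 1.5 times, and quantile normalization kept 83 and 86 of the calls, loess removal 78 and 85, and subtraction of the density drift 75 and 72. The number of lists standing apart, 1 in the original setting, was 3 with averaged probe sets, 4 without _x_at and _s_at probe sets, 4 after quantile normalization, 4 after loess removal, 5 with the higher floor, 4 without matching and 4 with matching on gene density. The hypoxia list stood apart in 7 of 9 alternatives, with percentiles from 0.19 to 13.7, and its median was -0.12 with averaged probe sets. The neuronal list stood apart without _x_at and _s_at probe sets (percentile 99.9), after quantile normalization (98.7), after loess removal (98.5), with the higher floor and with density matching (98.3), but lay at 97.0 without matching, 97.2 with equal medians, 70.8 with averaged probe sets (median 0.03) and 24.9 with no floor (median -0.02). Without _x_at and _s_at probe sets the sign turned for TLN1 (-0.42) and PCDH9 (0.026). In that setting only 34 of the 43 named or called list genes could be read. VIM, TMSB4X and TNFAIP3 were not among them. With averaged probe sets 23 of 43 named or called list genes moved by more than the SD between probe sets, and 17 fell short of 2-fold. Quantile normalization, loess removal or equal medians turned the sign of the small medians of the glycolysis, actin, unfolded protein response, receptor kinase, immediate early, ribosomal, heat shock and stem cell lists. A higher floor leaves fewer genes, and a threshold sets its own count; otherwise the cause was not tested. Alternatives for CA9 itself were not run, because no probe set is paired with it here. No paired analysis was possible because there is 1 array per line. Genes near the floor of 40.8 are the least certain, since their folds are bounds.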

Other observations

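The genes named in this part were chosen after their values were seen. TFPI, the tissue factor pathway inhibitor, was 2.27-fold lower in the CA9 line, with its 3 other probe sets between -1.79 and -1.23. Of these, 1 lay below the floor in the CA9 line, at least 2.55-fold lower. Its relative TFPI2 was 3.90-fold higher. YWHAE, a 14-3-3 protein, was 2.22-fold higher at 2757 against 1244, with a second probe set at 1.27.

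In a scan of 165 families of genes that share the letters at the start of their symbols, made after the data were seen, 9 families had medians below the middle 95% of random lists and 4 above it, against 8.25 expected on both sides together. The family farthest from its random lists was ZNF, the zinc finger genes, many of which are transcriptional repressors. Its 331 measurable members had a median of -0.16, below all 10000 random lists, whose middle 95% ran from -0.06 to 0.03, and 117 of 331 were above 0. Of these genes 8 were called, and 12.4% of random lists had as many, so the called members do not stand apart as the median does. Smaller families had lower medians, among them STK (20 genes) at -0.29, percentile 0.39, and VPS (37 genes) at -0.24, percentile 0.44. A lower median was therefore not particular to the ZNF family. ZNF22 was 2.85-fold lower, with a second probe set lower too but below the floor in the CA9 line, ZNF226 was 2.39-fold lower, with a second probe set at -0.51, and ZNF296 was 2.12-fold higher. TRIM28, the corepressor of many zinc finger proteins, was 2.15-fold higher at 3284 against 1524.

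The scan raised the hypothesis that zinc finger transcripts are lower as a class in the CA9 line, and its tests were chosen after the family was seen. A shift of chromosome 19, which holds 132 of them, is argued against as the whole cause, since the 199 outside it had a median of -0.11, at percentile 0.25 of random lists. Probe sets marked by name as shared are argued against as the whole cause. Without names ending in _x_at, _s_at or _a_at, 264 genes had a median of -0.16. No probe sequences were used, so signal from related zinc finger transcripts stays open. The drift with gene density is argued against as well. The family's median of -0.16 lay below all random lists matched on density too (middle 95% from -0.02 to 0.07). Base composition and transcript stability, which may set these genes apart from others of like intensity, were not tested. With 1 array per line, a difference in RNA handling and one in the cells stay open alike.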
